A study of Mus musculus with 4 samples.

How the data were processed

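RNA from 2 sorted mouse intestinal populations, Paneth cells and Lgr5 stem cells, was compared on 4 Agilent two-colour Whole Mouse Genome 4x44K arrays. Per the labels, RNA was extracted with Trizol, and 300 ng of total RNA per sample was amplified and labelled with the Agilent low RNA input linear amplification kit. Each sort pooled 10 mice and was hybridised with both dye assignments, so the sort was the replicate (n = 2) and the exchanged dyes were a technical repeat. The arrays of a sort were scanned together, so sort and scan cannot be told apart, and each ratio was formed within an array.

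Per the file headers, the spot values are scanner intensity in each channel, as mean spot signal, median local background and a processed signal that is background-subtracted and dye-normalised by the scanner software. The deposited value table holds log10 ratios with a median of 0 on each array. These equal the scanner's log10 Cy5 over Cy3 ratio with the sign turned by the authors on the 2 swapped arrays, with a largest difference in size of 5e-06. As a result the deposited columns of sort 1 are stem over Paneth and those of sort 2 Paneth over stem. The file headers name Feature Extraction 10.5.1.1, whereas the submitters' processing notes list Agilent Feature Extraction 9.5.3. Probe positions are those in the files, on the mouse build mm9.

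Each array held 45018 spots, of which 43379 were not controls, for 41174 probes, 245 of them printed at 10 spots each. Mean signals were corrected for the median local background with normexp at an offset of 50 and normalised by loess within each array with control spots at weight 0. Control spots and spots called non-uniform outliers by the scanner software were left out. Signs were turned so that Paneth was the numerator, the spots of a probe were averaged, and the dye-swapped arrays of a sort were averaged. A probe was kept if it was well above background in the channel of at least 1 population on at least 3 of 4 arrays, which left 19588 probes. The brightest kept probe stood for each gene, which left 14027 genes or unnamed features. Of these, 10744 were matched to a current symbol by accession and 1579 by name, 1704 kept only the name in the file, and 1603 symbols changed. Where no probe of a gene was well above background in 1 population on any array, the fold was given as a bound. The level of that population was then set on each array to the dimmest level that was well above background there, or to its own level if higher, with levels per channel after loess and Aquantile normalisation.

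Ratios over the 2 sorts were tested with a fit of the mean alone in limma 3.58.1 (lmFit and eBayes) under R 4.3.3, adjusted by Benjamini-Hochberg over all tested features at a threshold of 0.05. SE is limma's moderated standard error. The prior had 7.98 degrees of freedom and an SD of 0.289. No paired analysis was possible beyond this because both populations share every array and form a single group. Tables were read with the R packages data.table (version 1.17.8) and jsonlite (version 2.0.0), and plots were drawn with matplotlib 3.10.9 under python 3.11.15.

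A total of 24 gene lists, compiled from general knowledge, was fixed before the data were examined. They covered Paneth granule products, secretory transcription factors, Lgr5 and +4 stem cell genes, Wnt, EGF and Notch ligands with their receptors and targets, BMP genes, cell cycle, endoplasmic reticulum, ribosomal, glycolysis, oxidative phosphorylation and zinc genes. Further lists held goblet, enteroendocrine, tuft, enterocyte, blood and stromal cell markers. The 22 lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. Of the 12 lists past the threshold with the preset correlation, 0 passed with an estimated correlation (lowest adjusted p = 0.635) and 0 with fry (lowest adjusted p = 0.249, and 0.170 in either direction). At an unadjusted p under 0.05 the counts were also 0 and 0. List medians did not change with members below background set at their bounds.

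Genes to be named were chosen by a fixed rule with 4 parts. The rule took the 12 largest and 12 smallest ratios among genes past the threshold with a symbol, the same sign on all 4 arrays and both populations above background in each sort. It also took the 6 largest bounds per direction where 1 population was at background. From each list it took up to 4 members past the threshold in the direction most members took and up to 2 in the other, or the 2 largest where 0 passed. It always took Lgr5, Cd24a, Egf, Tgfa, Wnt3, Wnt11, Dll1, Dll4, Notch1, Egfr, Lyz1, Mmp7, Ascl2, Olfm4 and Mki67. Genes named outside the rule complete a small count or carry a further probe, and were chosen after their values were seen. The result of 1 member of the blood cell list is not reported here.

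On simulated data with few changed genes, the fit called 3.03% of genes changed by a log2 of 0.5, 17.9% of those changed by 1 and 100% of those changed by 2, and 5.81% of its calls were unchanged genes. With as many changed genes as were called in the data, the shares were 17.8%, 88.3% and 100%, and 3.11% of the calls were unchanged genes. With no changed gene 0 were called. The simulated spreads were drawn from the prior fitted to these data, and the simulated sorts had the same scale. In the data most called genes had larger ratios in sort 1, so these shares do not measure the error rate of the real calls. A simulated list shifted by a log2 of 1 was called by camera at the preset correlation. It had adjusted p values of 0.814 with an estimated correlation and 0.529 with fry, so those tests could not find such a shift with 2 sorts. The simulated genes varied independently, so the simulation does not check camera's p values on correlated genes. The values returned as estimated correlations ran from -0.20 for +4 genes to 0.80 for enteroendocrine markers, with 0.58 for Paneth granule products and 0.66 for cell cycle genes. With 2 sorts each gene has 1 residual, so these values reflect only how many members differed between the sorts in the same direction. They do not measure correlation between genes.

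Alternatives were tried for background correction, normalisation, the filter on dim probes, the treatment of outlier spots, the use of dye swaps, the variance prior, the choice among probes, the set test, the fold threshold and the source of the ratios, and each sort was left out in turn. A fit of the 4 arrays with a dye term used the sort as a block with a correlation of 0.756, computed from balanced mean squares because limma's own function returned no value with that term. A search for short sequences shared by probes with Paneth-side ratios was run on a random part of the probes and tested on the rest with Fisher's exact test. Control transcripts were left out of all fits.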

Results

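The series set Paneth cells against Lgr5-positive stem cells of the mouse small intestinal crypt, and its title names Paneth cells as the niche of those stem cells. Paneth cells are granulated secretory cells at the crypt base, and Lgr5 marks the cycling stem cells that sit between them. Both populations were sorted from Lgr5-EGFP-ires-CreERT2 mice, in which the Lgr5 locus drives GFP. Stem cells were taken as GFP-high cells, and Paneth cells as cells with high CD24 and high side scatter. Each of 2 sorts pooled 10 mice, and the labelled RNA of both populations from a sort was hybridised together on Agilent 4x44K mouse arrays. Each sort was hybridised again with the dyes exchanged, which gave 4 arrays in 1 group and n = 2 sorts. Of the 43379 non-control spots per array, Paneth RNA was well above background at 35.8% to 45.0% and stem cell RNA at 30.5% to 57.4%. No spot was saturated, and the number of arrays limits the precision. All ratios below are log2 Paneth over stem as mean ± SE over 2 sorts. The deposited value columns of sort 1 run the other way, stem over Paneth.

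The comparison asked which transcripts differ between Paneth cells and their neighbouring stem cells. Of 14027 genes and unnamed features tested, 2177 were higher in Paneth cells and 1270 were higher in stem cells at an adjusted p under 0.05 (limma, n = 2 sorts). The differences on the Paneth side were larger. The median log2 ratio was 1.15 among the Paneth-side genes and -0.89 among the stem-side genes, and 179 genes exceeded a log2 ratio of 3 on the Paneth side against 0 on the stem side. Ratios were larger in sort 1 than in sort 2 for 80.4% of the Paneth-side genes (medians 1.37 and 0.97) and for 95.9% of the stem-side genes (medians -1.18 and -0.63). With median centring in place of loess the median of all genes moved from -0.01 to -0.59, and the counts became 400 and 2025. Without the filter on dim probes 28307 features were tested, and 2 and 0 passed (3567 and 2586 at an unadjusted p under 0.05).

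**Figure D1:**
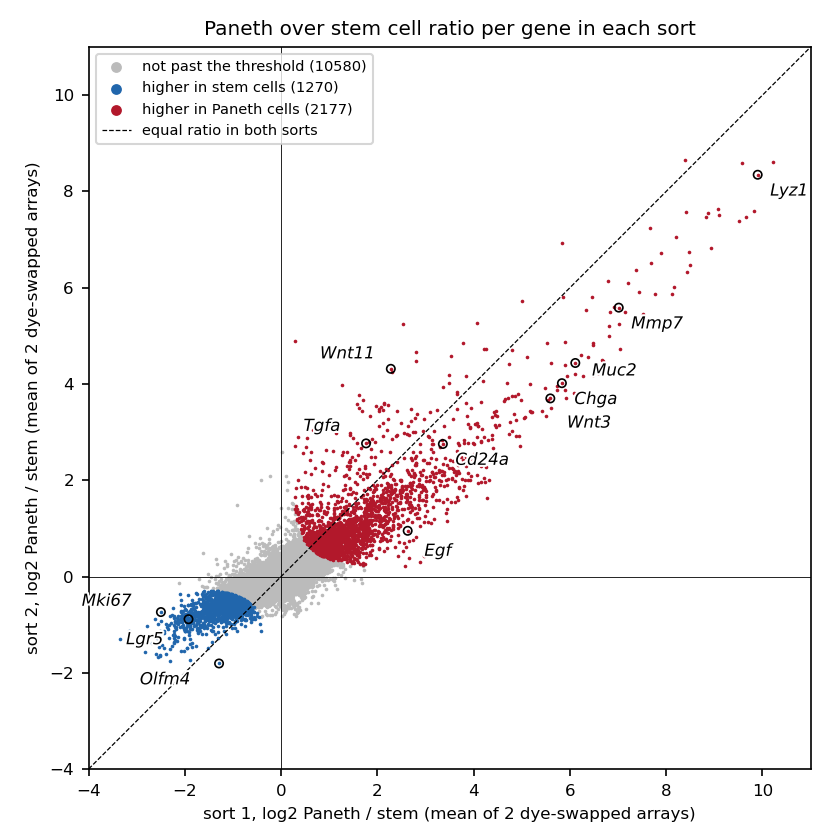
Each point is a gene, with its log2 Paneth over stem ratio in sort 1 on the x axis and in sort 2 on the y axis, each the mean of 2 dye-swapped arrays. Red and blue mark the 2177 genes higher in Paneth cells and the 1270 higher in stem cells, grey the 10580 others, and circles the labelled genes. The dashed line marks equal ratios, and most red and blue points lie nearer to the sort 1 axis than the line.

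Products of Paneth cell granules had the largest ratios of any list. Of 26 measured antimicrobial and granule genes 25 were higher in Paneth cells (25 adjusted over the list alone), with a median log2 ratio of 6.87. They included the alpha-defensins Defa20 (9.42 ± 0.33, 684-fold, adjusted p = 6.5e-07), Defcr4 (8.72 ± 0.42), Defa3 (8.56 ± 0.41), Defa21 (8.53 ± 0.20), Defa1 (8.31 ± 0.33), Defa23 (8.21 ± 0.29) and Defcr6 (8.15 ± 0.30). The bactericidal enzyme Lyz1, lysozyme, was 558-fold higher (9.12 ± 0.32), the secreted ribonuclease Ang4 329-fold (8.36 ± 0.31) and the lectin Itln1 255-fold (7.99 ± 0.24). Mmp7, the matrix metalloprotease that processes pro-defensins, was 78.8-fold higher (6.30 ± 0.31). Reg3a was the member that did not pass (0.26). The shift of the list had an adjusted p of 1.79e-31 by camera, and adjusted p = 0.635 with an estimated correlation. Defensin probes can hybridise to near-identical family members, so single defensin genes are uncertain.

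Among genes outside the lists Prm1, which encodes a protamine of sperm chromatin, had a log2 ratio of 9.09 ± 0.25, and Npff, a neuropeptide gene, 7.88 ± 0.40. The other 2 Prm1 probes read 0.83 and 0.01, the latter at background on all 4 arrays. The probes used for Prm1 and Npff hold short sequences, GCCGCC and GTGCCC, that were shared by unrelated probes with Paneth-side ratios. Stem cell RNA was not well above background on any array for Lamb1, a laminin chain, Samd5, Olfr112, an olfactory receptor gene, Copz2, a COPI coat subunit, Gfi1 and Habp2, so their folds are bounds. Lamb1 was at least 7.49-fold higher in Paneth cells, Samd5 at least 7.19-fold, Olfr112 at least 6.95-fold, Copz2 at least 6.90-fold, Gfi1 at least 6.74-fold and Habp2 at least 6.71-fold. These bounds are means over the sorts, and those of Olfr112 were 6.31 and 7.65 in sorts 1 and 2, but those of Lamb1 were 18.1 and 3.09, Samd5 10.7 and 4.84, Copz2 13.7 and 3.49, Gfi1 11.1 and 4.08, and Habp2 9.74 and 4.63.

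Transcription factors of the secretory lineage were higher in the Paneth fraction as well, 11 of 13 measured, with a median of 1.67 and 0 lower (11 adjusted over the list alone, and 5 over all genes with median centring). Goblet and enteroendocrine cells share several of these factors, and their markers were also higher in this fraction, with medians of 3.88 and 2.83. Bhlha15, a regulator of secretory cell structure whose further probe read 1.03, reached 5.57 ± 0.42, Spdef, a regulator of Paneth and goblet cell maturation, 4.55 ± 0.40, Creb3l4 3.98 ± 0.32 and Klf4 2.99 ± 0.19. Foxa1 (0.34) and Neurog3 (0.28) did not pass. The list's adjusted p was 4.21e-09 by camera and adjusted p = 0.635 with an estimated correlation.

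The largest mean stem-side ratios among genes above background in both populations were those of Cps1, a mitochondrial carbamoyl phosphate synthetase (-2.33 ± 0.39, 5.01-fold, adjusted p = 0.00324, -3.35 and -1.30 in the sorts), Acot1, an acyl-CoA thioesterase (-2.20 ± 0.29), Gvin1, a very large interferon-inducible GTPase (-2.15 ± 0.39), Stmn1, a microtubule regulator (-2.11 ± 0.24), Cdca7 (-2.11 ± 0.26) and Sp5, a Wnt target transcription factor (-2.07 ± 0.24). Next came Mpzl2 (-2.04 ± 0.29), Edn1, the endothelin-1 precursor (-2.04 ± 0.21), Arl4c (-2.01 ± 0.23), the potassium channel gene Kcnq1 (-2.53 in sort 1 and -1.47 in sort 2), Prelp (-1.96 ± 0.25) and Uhrf1, which maintains DNA methylation (-1.95 ± 0.28). The order depended on the sort, and in sort 2 alone Olfm4 and Edn1 led. Where Paneth RNA was not well above background on any array, Cttnbp2 was at least 2.42-fold higher in stem cells, Cyp4f15 at least 1.82-fold, Pcdh8 at least 1.82-fold, D7Ertd715e at least 1.78-fold, Kif15 at least 1.77-fold and Rassf5 at least 1.73-fold. In sort 2 alone these bounds were 1.60, 1.38, 1.27, 1.44, 1.24 and 1.35.

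The genes used for sorting followed their populations. Lgr5 was 2.65-fold higher in stem cells (-1.40 ± 0.26, adjusted p = 0.00499), with -1.92 in sort 1 and -0.89 in sort 2. Its probe lies on chromosome 10 at 114888847 to 114888906 of the mouse build mm9, and a probe for another part of the gene was not above background. Cd24a was 8.32-fold higher in Paneth cells (3.06 ± 0.22, 3.36 and 2.75 in the sorts).

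Of 30 measured genes on the Lgr5 stem cell list, 19 were higher in stem cells, 1 was higher in Paneth cells and 10 did not pass (21 and 1 adjusted over the list alone). The list was compiled from knowledge of Lgr5 cells, and earlier profiles of this kind of sort enter that knowledge. Besides Cdca7 and Sp5, Scn2b (-1.85 ± 0.24), Slc14a1 (-1.82 ± 0.21), Olfm4, a secreted glycoprotein (-1.55 ± 0.21), and Ascl2, a transcription factor of stem cell identity (-0.99 ± 0.20), were lower in Paneth cells. A further Olfm4 probe read -2.69. Phlda1 went the other way (0.95 ± 0.20), but its ratio was -0.21 with median centring, where all genes lay at -0.59. The list's adjusted p was 5.4e-09 by camera and adjusted p = 0.635 with an estimated correlation. Of the 5 measured genes assigned to the +4 position stem cell, Mex3a was higher in stem cells (-0.87 ± 0.22) and Hopx (0.50), Tert (0.34), Bmi1 (0.16) and Lrig1 (-0.55) did not pass. That list's median of 0.16 and mean of -0.08 differ in sign, its adjusted p was 0.764, and its median was -0.68 with median centring.

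Of 44 measured cell cycle genes, 32 passed on the stem side, 0 on the Paneth side and 12 did not pass (38 and 0 past the threshold adjusted over the list alone), with a median of -1.37. The replication licensing genes Mcm4 (-1.90 ± 0.29) and Cdt1 (-1.80 ± 0.26), the mitotic kinesin Kif20a (-1.86 ± 0.30), the condensin subunit Ncapg (-1.78 ± 0.29) and the proliferation marker Mki67 (-1.62 ± 0.35) were among them. Mki67 read -2.50 in sort 1 and -0.74 in sort 2, and the list's medians were -1.75 and -0.82. Its adjusted p was 1.59e-17 by camera and adjusted p = 0.635 with an estimated correlation.

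The ligand comparison asked which genes of the Wnt, EGF and Notch ligand families were higher in Paneth cells. Whether the product of each gene, Dll3 included, reaches or activates a neighbouring cell was not measured. Of 15 measured ligand genes, 7 were higher in Paneth cells and 1 was higher in stem cells. The count on the Paneth side was 4 with median centring, namely Wnt3, Wnt11, Tgfa and Dll3. It was 3 with a stricter filter on dim probes and 0 without a filter. Wnt3, a ligand of canonical Wnt signalling, was higher in Paneth cells (4.65 ± 0.37, adjusted p = 4.84e-05, 5.59 and 3.70 in the sorts). Its probe lies on chromosome 11 at 103677409 to 103677468 (mm9), and a further Wnt3 probe read 2.54. Wnt11 was 9.83-fold higher (3.30 ± 0.39, adjusted p = 0.000454), with 2.28 in sort 1 and 4.31 in sort 2. Its only probe, on chromosome 7 at 106001985 to 106002045, holds GTGCCA, a sequence related to one shared by unrelated Paneth-side probes. Wnt5b (0.28), Wnt6 (-0.04), Wnt9b (-0.04) and Wnt7b (-0.10) did not pass. The shift of the 6 Wnt ligands had an adjusted p of 0.154 by camera. With median centring their median was -0.19, which was 0.40 above the median of all genes, and the list passed (adjusted p = 0.000376 by camera).

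Egf, the founding EGF receptor ligand, was 3.46-fold higher in Paneth cells (1.79 ± 0.34, adjusted p = 0.00567, 2.63 and 0.95 in the sorts). Its probe lies on chromosome 3 at 129380826 to 129380885 (mm9), where stem RNA was well above background on 2 of 4 arrays. The Egf call was lost with median centring. Tgfa, another EGF receptor ligand, read 2.27 ± 0.26 (4.81-fold, adjusted p = 0.000348), with 1.77 in sort 1 and 2.77 in sort 2. The Tgfa probe used, on chromosome 6 at 86224838 to 86224897, holds the shared sequence GTGCCC. A further Tgfa probe was not above background in Paneth RNA and read -0.06. Hbegf, the heparin-binding family member, was higher in stem cells (-1.35 ± 0.23), and Areg (-0.48) and Nrg4 (-0.70) did not pass. Over the 5 EGF family ligands the median was -0.48 and the mean 0.30, so they differ in sign, and the adjusted p by camera was 0.843. Adjusted over the list alone 2 were higher in each population.

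Of 4 measured Notch ligands, Dll3 (2.01 ± 0.33), Dll4 (1.63 ± 0.24) and Dll1 (0.71 ± 0.20) were higher in Paneth cells and Jag1 (-0.15) did not pass. Dll4 was 3.10-fold higher (adjusted p = 0.00165, 2.07 and 1.19 in the sorts), and its probe lies on chromosome 2 at 119160779 to 119160838. The Dll4 call was lost with median centring. Dll1 was 1.63-fold higher (adjusted p = 0.0335), but was -0.17 with median centring, where it was 0.42 above the median of all genes. Adjusted over the list alone the Notch and Wnt ligand counts were unchanged at 3 and 2. Lists of fewer than 5 measured members were given no set test.

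**Figure D2:**
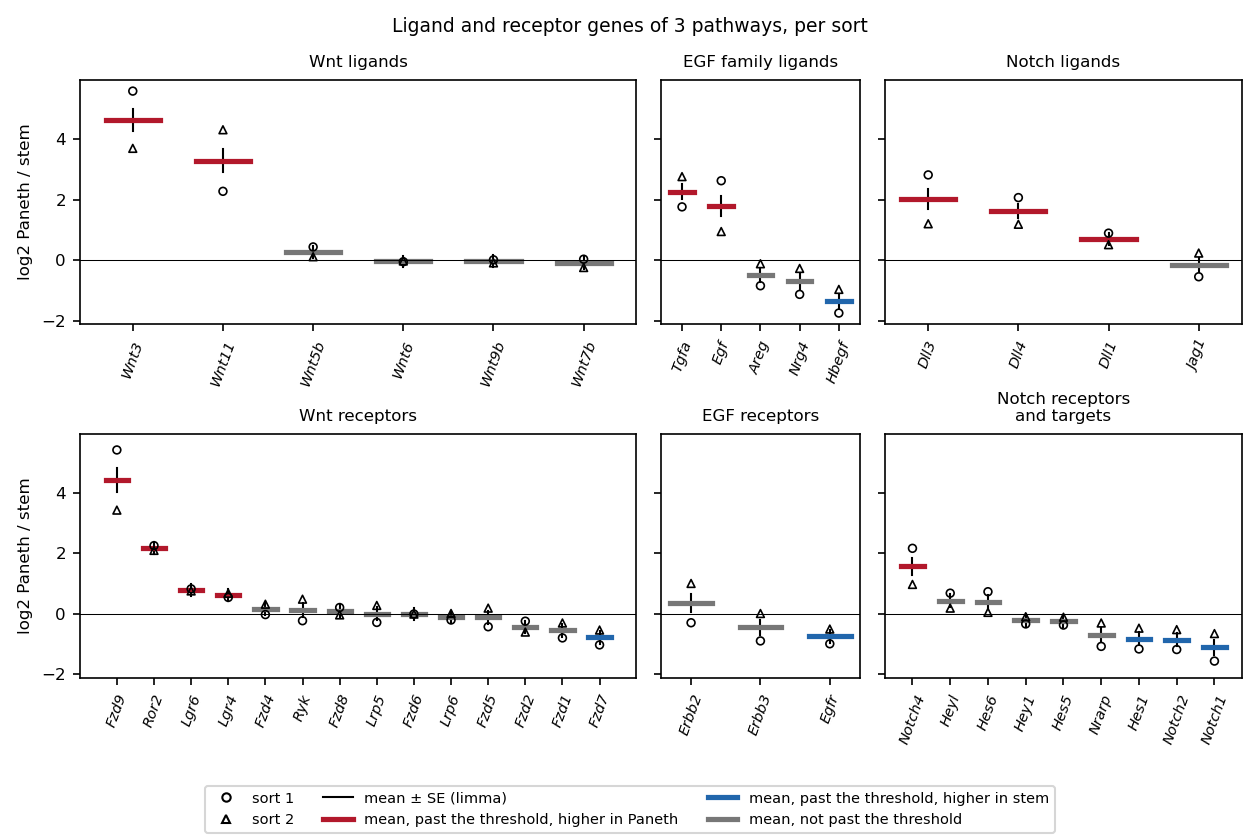
Log2 Paneth over stem ratios of the measured ligand, receptor and target genes of the Wnt, EGF and Notch pathways. Horizontal bars are means of 2 sorts with limma's SE as vertical lines, circles are sort 1, triangles sort 2, and red and blue bars mark genes past the threshold. Wnt3 stood at 4.65 and Fzd9 at 4.42, and Notch1 (-1.11) and Hbegf (-1.35) were on the stem side.

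Among 14 Wnt receptors 4 were higher in Paneth cells and 1 in stem cells, with an adjusted p of 0.543 by camera. Fzd9 was 21.4-fold higher in Paneth cells (4.42 ± 0.38), Ror2 read 2.18 ± 0.19 on a probe that holds GTGCCC, and Lgr4 read 0.61 ± 0.19 (adjusted p = 0.0488). The other was Lgr6, whose stem signal on the probe used was not above background on any array, so no ratio is given. Lgr4 was -0.35 with median centring, 0.24 above the median of all genes. Fzd7 read -0.78 ± 0.21, but its 2 kept probes read -0.78 and 0.99, and both passed. Of 3 EGF receptor genes Egfr was higher in stem cells on the probe used (-0.75 ± 0.21), 2 further kept probes read 0.42 and 0.46, and Erbb2 (0.35) and Erbb3 (-0.44) did not pass. Of 9 Notch receptors and targets, Notch1 (-1.11 ± 0.25), Notch2 (-0.85 ± 0.22, although a further kept probe read 0.50) and the target Hes1 (-0.82 ± 0.22) were higher in stem cells and Notch4 (1.57 ± 0.28) in Paneth cells, with an adjusted p of 0.283 for the list. The median of this Notch list was -0.24, against -1.51 with Agilent's processed signals and -1.34 from the authors' table. Of 13 BMP pathway genes, the targets Id1 (-1.92 ± 0.29), Id2 (-1.33 ± 0.22) and Id3 (-1.03 ± 0.20) were higher in stem cells. The ligands Bmp7 (1.84 ± 0.21) and Bmp4 (1.60 ± 0.38, 0.61 and 2.59 in the sorts) were higher in Paneth cells, and the list's adjusted p was 0.407. Adjusted over the list alone, the Notch receptor and target counts were 4 on the stem side and 1 on the Paneth side, and the BMP counts were 3 and 3. Those of the Wnt and EGF receptors were unchanged. Of 17 Wnt target genes 7 were higher in stem cells and 4 in Paneth cells (9 and 4 adjusted over the list alone). Sp5, Tnfrsf19 (-1.61 ± 0.21), Myc (-1.56 ± 0.32) and Cd44 (-1.35 ± 0.27) led the stem side, and Mmp7 and Nkd1, a feedback inhibitor (2.99 ± 0.30), the Paneth side. The median of this list was -0.62 and its mean 0.06, and its adjusted p was 0.154.

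Genes of protein folding and export in the endoplasmic reticulum were higher in Paneth cells. Of 39 measured, 38 passed (38 adjusted over the list alone), with a median of 1.73 and quartiles of 1.23 and 2.15, and only Canx (-0.14) did not. The protein disulfide isomerase subunit P4hb was 11.1-fold higher (3.48 ± 0.27), the co-chaperone Dnajc3 9.80-fold (3.29 ± 0.26), Herpud1, a part of the degradation machinery, 7.66-fold (2.94 ± 0.20) and the oxidase Ero1b 7.51-fold (2.91 ± 0.36). With median centring 4 passed and the median was 0.69, which was 1.28 above that of all genes. The list's adjusted p was 2.17e-22 by camera and adjusted p = 0.635 with an estimated correlation.

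Cytosolic ribosomal protein genes lay on the stem side, with 35 of 78 past the threshold there, 0 on the Paneth side and a median of -0.62 (45 and 1 adjusted over the list alone). The stem-side count depended on the processing, with 9 at a normexp offset of 10, 1 with Agilent's processed signals, 1 from the authors' table and 76 with median centring, where the median was -2.05. Rpl27a (-1.34 ± 0.26), Rpl14 (-1.32 ± 0.22), Rps9 (-1.09 ± 0.23) and Rpl4 (-1.05 ± 0.20) had the largest stem-side ratios. The adjusted p was 1.4e-13 by camera and adjusted p = 0.635 with an estimated correlation. Of 74 nuclear-encoded oxidative phosphorylation genes 10 were higher in stem cells, 2 in Paneth cells and 62 did not pass, and adjusted over the list alone the counts were 1 and 2. The electron transport subunits Ndufb5 (-1.04 ± 0.21), Cyc1 (-0.81 ± 0.22), Cox6b1 (-0.78 ± 0.22) and Cox6c (-0.78 ± 0.25) were on the stem side. Cox7a1 (0.98 ± 0.20) and Ndufa1 (0.87 ± 0.19) were on the Paneth side, but read -0.01 and -0.45 with median centring, 0.58 and 0.15 above the median of all genes. The list's median was -0.39 and its adjusted p 4.92e-06 by camera, against adjusted p = 0.689 with an estimated correlation. The camera p was 0.0744 with Agilent's processed signals, where 1 gene passed on the stem side, against 51 with median centring.

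Glycolysis genes did not shift as a list (22 measured, adjusted p = 0.754, median -0.11 and mean 0.05). Of these, 4 were higher in Paneth cells, Hk1, a hexokinase (1.82 ± 0.23, with a further kept probe at 0.43), Aldoa (0.94 ± 0.19), Pfkfb3 (0.87 ± 0.20) and the lactate exporter Slc16a3 (0.64 ± 0.20). Aldoa was -0.42 with median centring, 0.17 above the median of all genes, and 3 genes were higher adjusted over the list alone. With median centring 0 glycolysis genes passed on the Paneth side and 4 on the stem side. Among zinc transporters and metallothioneins 9 of 23 were higher in Paneth cells and 0 in stem cells (9 and 1 adjusted over the list alone), with a median of 0.41. Slc30a2, a vesicular zinc importer, was 8.07-fold higher (3.01 ± 0.35), Slc39a11 5.52-fold (2.46 ± 0.21), Slc39a7 5.28-fold (2.40 ± 0.25) and Slc30a7 2.60-fold (1.38 ± 0.23). The metallothionein genes Mt1 (-0.56) and Mt2 (-0.46) did not pass. The list's adjusted p was 0.00705 by camera and adjusted p = 0.635 with an estimated correlation. With median centring the list's median was -0.31, 0.28 above that of all genes, with an adjusted p of 0.137, and 1 gene was higher in Paneth cells and 2 in stem cells.

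Markers of other cell types that the gates could hold were measured beside these groups. Of 13 goblet cell markers 12 were higher in the Paneth fraction, with a median of 3.88. Ccl6 (7.38 ± 0.40), Spink4 (6.67 ± 0.32), Reg4 (5.88 ± 0.43) and the mucin Muc2 (5.27 ± 0.34) led, and Clca3a1 was higher in stem cells (-1.40 ± 0.30). Clca3a1 entered the list through an older name in the file and may not be the goblet gene meant. Of 20 enteroendocrine markers 17 were higher in the Paneth fraction, with a median of 2.83. The hormone genes Gip (5.64 ± 0.34) and Sct (5.58 ± 0.41) and the chromogranins Chgb (5.42 ± 0.42) and Chga (4.92 ± 0.36) led, although a further Chgb probe was at background. Of 10 tuft cell markers 8 were higher in the Paneth fraction, with a median of 0.94 (0.57 and 1.27 in the sorts). Of the tuft cell markers 2 passed without background subtraction and 0 with median centring, where their median was 0.88, 1.47 above that of all genes. At a normexp offset of 10, 9 passed (median 1.40). With Agilent's processed signals 9 passed, and 8 did with the authors' ratios (median 2.96 for each). Alox5ap read 1.55 ± 0.20 and Trpm5, a taste-signalling channel, 1.18 ± 0.23, and Ptgs1 was at least 2.32-fold and Rgs13 at least 2.07-fold higher, with bounds of 3.23 and 1.67 for Ptgs1 and 1.48 and 2.90 for Rgs13 in sorts 1 and 2. The adjusted p values by camera were 3.73e-12 for goblet, 9.92e-15 for enteroendocrine and 8.61e-05 for tuft cell markers, and each had adjusted p = 0.635 with an estimated correlation.

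Of 21 enterocyte markers 7 were higher in the Paneth fraction and Dpp4 was higher in stem cells (-1.05 ± 0.25). Slc2a5, a fructose transporter (2.68 ± 0.26), Krt20 (2.65 ± 0.20), Apob (2.31 ± 0.19) and Anpep (1.70 ± 0.20) led. The Apob probe holds GTGCCA, and 2 further kept Apob probes read -0.22 and -0.20. This list's median was 0.19 (0.15 in sort 1 and 0.81 in sort 2), its adjusted p was 0.0341 by camera and adjusted p = 0.689 with an estimated correlation. The call was lost with Agilent's processed signals (adjusted p = 0.0744), and with median centring the median was -0.02, 0.57 above that of all genes. The 8 measured blood cell markers did not shift as a list (median -0.02 and mean 0.23, which differ in sign, adjusted p = 0.736). Among 5 stromal and endothelial markers Vim (2.05 ± 0.22) and Tagln (0.86 ± 0.22) passed (adjusted p = 0.154 for the list). Adjusted over the list alone, 18 enteroendocrine, 9 tuft, 9 enterocyte, 12 goblet and 2 stromal cell markers were higher in the Paneth fraction, and Clca3a1 and Dpp4 were higher in stem cells. Of the other-type list members past the threshold over all genes, only Clca3a1 and Dpp4 were on the stem side.

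**Figure D3:**
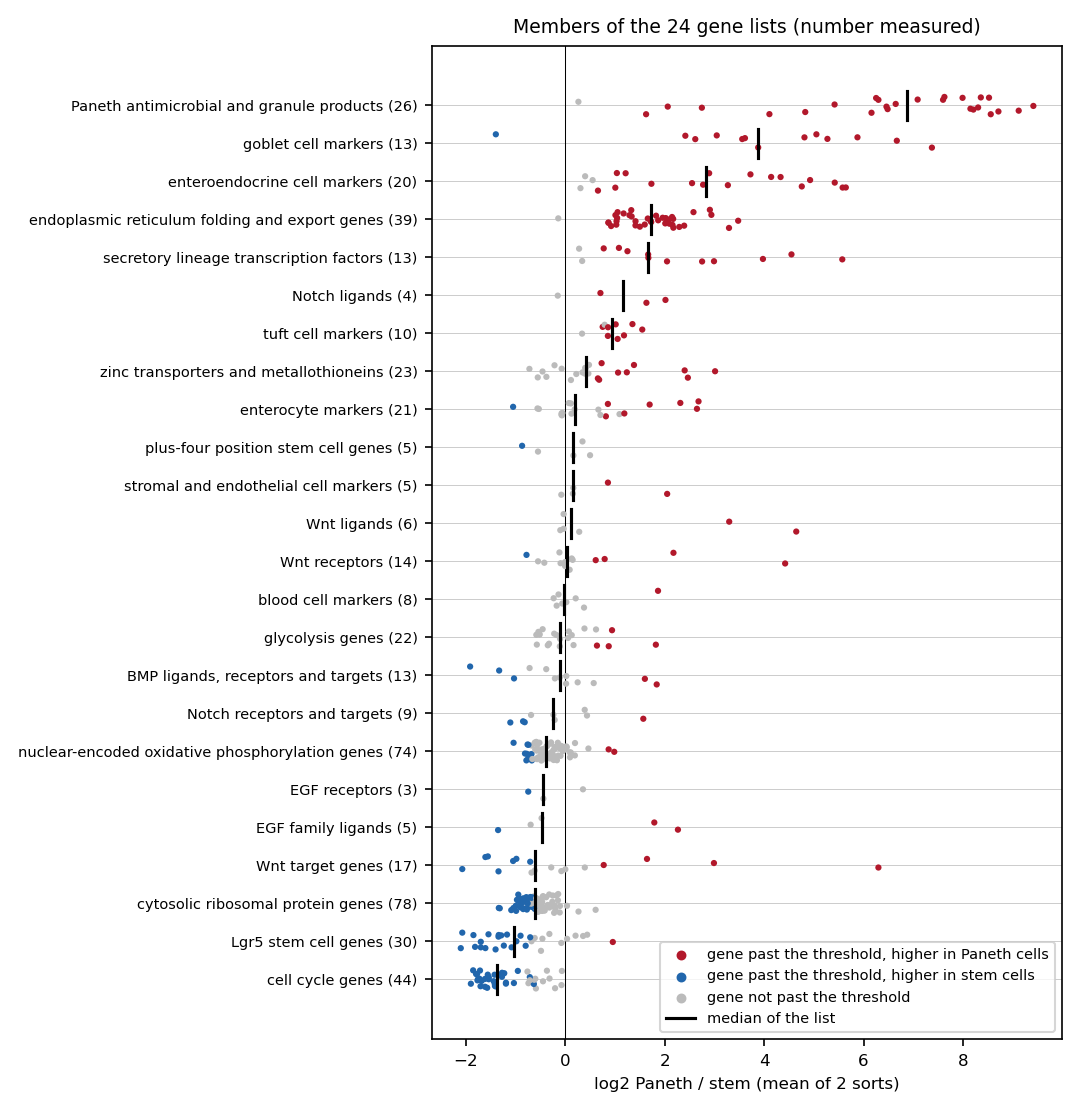
Log2 Paneth over stem ratio (x axis, mean of 2 sorts) of each measured member of the 24 gene lists (rows, number measured in parentheses, points spread vertically for legibility). Red and blue points are genes past the threshold, grey points are others, and black lines are list medians. Medians ran from 6.87 for Paneth granule products to -1.37 for cell cycle genes.

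The sorts and dyes were compared as a check on direction and spread, across genes, which are not independent replicates. Ratios turned the same way correlated at r = 0.961 between the dye-swapped arrays of sort 1 and 0.925 between those of sort 2. Between the sorts r was 0.889, with 79.8% of genes on the same side. Unturned Cy5 over Cy3 ratios of dye-swapped arrays correlated negatively (-0.817 and -0.576), as exchanged dyes require. Of 4292 genes with more than 1 kept probe, 1079 had ratios of both signs and 10 had calls in both directions, Fzd7 among them. Further kept probes read nearer 0 than those used for Arl4c (-0.30), Prelp (-0.18), Cd44 (-0.14), Ncapg (-0.48), Mpzl2 (-0.71), Dnajc3 (1.68) and Muc2 (2.12 and 1.76).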

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

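The array values of 10 array measures, 24 list medians and 124 named genes were searched for an array far from the other 3, and the control transcripts added to the RNA were read as data outside the main measurement. If all arrays were independent, chance would single out about 1 in 20 such groups, or 0.5, 1.2 and 6.2 of them. The search found 0, 1 and 1. The arrays were dye-swapped repeats of the same sorts and so were not independent. The chance counts are thus not the numbers to expect here, and no conclusion is drawn from the comparison. No explanation was tested for these results.

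The median of the glycolysis genes was 0.01 on the sort 2 array with Paneth RNA in Cy3 and -0.17, -0.15 and -0.14 on the others. The gap took up 0.853 of the whole range. Id3, a target of BMP signalling, had a log2 ratio of -0.71 on the sort 2 array with Paneth RNA in Cy5 and -1.13, -1.14 and -1.16 on the others, a gap of 0.932 of the range.

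Control transcripts are added to each RNA at labelling. Over 10 such probes in sort 1, the median unnormalised log2 ratio of Paneth over stem was 2.82 (7.07-fold, 2.30 to 3.12 between probes), while that of the genes was -1.72. In sort 2 the control probes had a median of -0.45 (-0.56 to -0.19) and the genes -0.25. Each probe value is the mean of 2 dye-swapped arrays. On the sort 1 array with Paneth RNA in Cy5 alone, the control probes ran from -0.23 to 5.76. The arrays hold no sample without these transcripts. Normalisation within arrays removes such a shift of all genes, so the ratios reported give no measure of total RNA per cell.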

How the results depend on the processing

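The alternative that left out probes with either enriched sequence was chosen after the data were seen, and the others were planned. Median centring moved the median of all genes to -0.59, and Agilent's processed signals and the authors' table moved it to -0.14, from -0.01. With median centring 400 genes were higher in Paneth cells and 2025 in stem cells (16.5% of calls on the Paneth side against 63.2%), 4 ligands were higher in Paneth cells and r between sorts was 0.852. Of the 3447 called genes 2955 kept their sign there, and 3439 did relative to the median of all genes. Medians turned to -0.68 for +4 genes, -0.19 for Wnt ligands, -0.31 for zinc genes, -0.0208 for enterocyte markers and -0.42 for Wnt receptors. Relative to the median of all genes, that of +4 genes was -0.09. The others lay above it, by 0.40, 0.28, 0.57 and 0.17. Phlda1 (-0.21), Dll1 (-0.17), Lgr4 (-0.35), Aldoa (-0.42), Cox7a1 (-0.0125) and Ndufa1 (-0.45) turned as well, but each lay above the median of all genes (by 0.38, 0.42, 0.24, 0.17, 0.58 and 0.15).

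Without a filter on dim probes 28307 features were tested, the prior fell to 2.21 degrees of freedom from 7.98, and 2 genes were higher in Paneth cells, 0 in stem cells and 0 ligands passed (limma, 3567 and 2586 at an unadjusted p under 0.05). All 3447 called genes kept their sign. Medians turned for EGF ligands (0.0319), BMP genes (0.0146) and blood cell markers (0.0222). A stricter filter tested 8927 genes, left 721 Paneth-side and 113 stem-side calls untested, gave 3 ligands and an r of 0.914.

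Stem-side calls were 804 without background subtraction, 822 at an offset of 10 and 809 from the authors' table. The 4 arrays as separate replicates gave 3430 and 2769 calls, which counts technical repeats as replicates. A fold of at least 2 left 1323 and 466 genes, and limma's treat against a log2 ratio of 1 gave 483 genes higher in Paneth cells and 8 genes higher in stem cells. With only Cy5 Paneth arrays r was 0.854 and the median of blood cell markers 0.0225, and with only Cy3 Paneth arrays that median was 0.0054 and that of Wnt receptors -0.11. The latter was -0.28 with Agilent's processed signals, -0.28 from the authors' table and -0.0044 without the sequence-bearing probes. The mean of all kept probes turned Fzd7 to 0.10 and Egfr to 0.0443, since their probes differ in sign. With an estimated correlation 0 lists passed, and 0 with fry. Except where the construction of the alternative shows it, the cause was not tested.

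Of 124 named genes 8 changed sign under at least 1 of 17 tested alternatives and 123 lost the call, 50 of them with the unfiltered test set aside. No called gene was called in the opposite direction under these 17 alternatives. With every kept probe tested, 10 genes had calls in both directions, Fzd7 among them. Among lists past camera's threshold, enterocyte markers lost it under 6 alternatives (adjusted p from 0.0505 to 0.0974) and oxidative phosphorylation genes under 2 (0.0744 and 0.0740), besides the other set tests. Enterocyte (0.0558) and zinc (0.137) lists also lost it with median centring. The Wnt ligand list, not past it in the main fit, passed with median centring (adjusted p = 0.000376 by camera). Leaving out a sort leaves no residual degrees of freedom, so it gave values with no test and no counts. Genes near background in 1 population are limited by signal over background: 100 Paneth-side calls had no stem signal above background on any array, and 14 stem-side calls no Paneth signal.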

Other observations

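Of the tests in this part, only that for residual background among the stem-side calls was chosen before its result was seen. The gene families in the next paragraph were drawn up after reading the list of called genes, so their counts describe that list and are not independent tests of it.

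Coat and cargo genes of transport between endoplasmic reticulum and Golgi had 24 of 33 members higher in Paneth cells and 1 higher in stem cells, with a median log2 ratio of 1.12 (0.08 with median centring, where 4 and 1 passed). They were led by Tmed6 (3.62), Tmed3 (3.31) and Tmed9 (2.16), with Tmed1 (-1.65) on the stem side. The Tmed3 probe holds GTGCCC, a sequence shared by unrelated Paneth-side probes, and 22 members passed without such probes. GalNAc and sialyl transferases had 11 of 17 higher and 1 lower, with a median of 0.87 (0.28 with median centring, where 2 and 1 passed), St3gal1 (3.96) and Galnt6 (2.17) among them. Families past camera's threshold whose medians turned negative with median centring, but stayed above the median of all genes of -0.59 there, were amino acid and serine synthesis (6 of 12 higher, median 0.80, turned to -0.05), amino acid transporters (13 of 34 higher and 3 lower, 0.47, -0.22), aminoacyl-tRNA synthetases (10 of 20 higher, 0.60, -0.39), lysosomal proteins (10 of 18 higher and 1 lower, 0.77, -0.30) and cholesterol synthesis (7 of 18 higher, 0.59, -0.35). Chac1 (4.30), Pycr1 (2.53), Asns (2.25), Wars (1.89), Lgmn (3.38), Lamp2 (2.84) and Hmgcs1 (1.74, on a probe with one of the sequences weighed here) were among these, and Ctss (-1.49) was on the stem side. With median centring the counts higher and lower in Paneth cells were 2 and 0 for amino acid synthesis, 3 and 3 for amino acid transporters, 1 and 1 for tRNA synthetases, 2 and 1 for lysosomal proteins and 0 and 1 for cholesterol synthesis.

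Of 78 mitochondrial ribosomal protein genes 17 were higher in stem cells and 0 in Paneth cells (median -0.46), against 6 at a normexp offset of 10, 3 with Agilent's processed signals, 1 from the authors' table and 45 with median centring. Ribosome biogenesis genes had 12 of 39 (-0.33, with Npm1 at -1.33, but 6 at an offset of 10, 3 with processed signals and 1 from the authors' table), chaperonin subunits 5 of 9 (-0.73, but 0 at an offset of 10 or with processed signals) and proteasome subunits 3 of 37 (-0.14, with Psmb8 at -1.10, but 0 with processed signals and 14 with median centring). With processed signals the medians of ribosome biogenesis, chaperonin and proteasome genes were -0.58, -0.85 and -0.20, where that of all genes was -0.14. Chemokines (2 of 10 higher in Paneth cells and 1 in stem cells), interferon-induced genes (6 and 5 of 32), claudins (2 and 0 of 11), Hox genes (1 and 0 of 6) and ion channel genes (11 and 7 of 41) did not pass camera's threshold, and the medians of the first 3 and of ion channel genes turned from above 0 to below it with median centring. These medians stayed above that of all genes there, by 0.10, 0.28, 0.39 and 0.45. With an estimated correlation the lowest adjusted p of all 16 families was 0.604, and with fry it was 0.227.

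Stem-side ratios stayed small, and Lgr5 kept a level in the Paneth fraction of 26.4% of its stem cell level in sort 1 and 54.1% in sort 2. Residual background in dim spots may shrink such ratios, since over all 74 measured members of the Lgr5 and cell cycle lists the median size in the brightest part exceeded that in the dimmest by 0.847 on the log2 scale (1.56 and 0.72, bootstrap interval 0.523 to 1.097). Among the stem-side calls the same difference was 0.0248 (0.885 and 0.861, interval -0.0133 to 0.0714), but a call needs a large ratio, so the planned threshold for that test cannot count against background. Both intervals came from resampling genes, which are not independent replicates, and do not measure the spread between sorts. The size also depended on the processing, which added an offset of 50. Relative to all genes, the Lgr5 and cell cycle list medians were -1.03 and -1.37. They were -1.25 and -1.47 at an offset of 10, and -1.38 and -1.65 with Agilent's processed signals. Stem cells in the Paneth fraction could set a floor common to all stem cell genes, and 88 and 89 stem-side genes lay below Lgr5 on both arrays of a sort, but only 2 in sort 1 and 0 in sort 2 lay under 50% of its ratio, and the 10 lowest had medians of 17.1% and 33.6%. A share of stem cells and expression of these genes by Paneth cells cannot be told apart, the latter was not tested, and brightness also differs between genes for biological reasons.

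Enteroendocrine, goblet and tuft cell markers were higher in the Paneth fraction. A lower share of stem cells would raise the markers of every other type present alike. The median of the goblet and enteroendocrine markers was 3.56 and that of enterocyte, blood and stromal markers 0.16 (quartiles -0.07 and 0.86). The markers thus did not all rise alike, with a gap of 3.40 for these and of 0.78 for tuft markers (median 0.94). Cell types scarce in both fractions would read near 0 at any share of stem cells, so neither gap can exclude a lower share. The tuft gap depended on the processing and was tested in the main fit only. With Agilent's processed signals the tuft median was 2.96, and those of enterocyte, blood and stromal markers were 0.34, -0.36 and 0.68. Enteroendocrine cells inside the gate are a candidate source. Of the measured genes, 8 of 8 hormone genes and 17 of 20 markers passed, with Paneth-fraction log2 levels of 15.01 for Sct and 14.06 for Gip. A gene dim in stem cells was measured only if it was well above background in the Paneth fraction. The filter thus favoured these counts, and they cannot decide the source. Which cells the gate for high side scatter held was not measured. Expression of each enteroendocrine, goblet and tuft marker by Paneth cells themselves was not measured either and stays open. Cck and Chgb each have a further probe at background.

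Genes outside the fixed lists, Prm1 among them, had Paneth-side ratios above a log2 of 4, as large as those of Paneth cell products. Their own transcripts would raise other probes of the same genes too, but of the 25 such genes with another probe only 5 (Rnase1, Defa39, Tspan1, Syt13 and Ces1c) had it above a log2 of 1, against 7 of 9 list genes (Fisher's exact p = 0.0037), which argues against it for the group but not for these 5. Cross-hybridisation through a short shared sequence is a candidate explanation, since GTGCCCT, found in a random part of the probes, was carried by 40 probes in the rest, of which 57.5% lay above 1 against 3.68% of the others (odds ratio 35.4, Fisher's exact p = 6.89e-23). Of 117 probes in the rest with its core GTGCCC 40.2% lay above 1 (odds ratio 18.6), and of 48 with GCCGCC 29.2% did (odds ratio 11.4), while of 216 with GTGCCA, looked up after its presence in the Wnt11 probe was seen, 6.94% did (odds ratio 2.07). Probes with GTGCCC carried 109 of the Paneth-side calls (5.01%) and 11 of the 95 above a log2 of 4, but of the 56 genes outside the lists above 4 only 17 hold GTGCCC or GCCGCC (30.4%, against 1.72% of the other tested genes), and 4 hold GTGCCCT, so these sequences are not the whole cause, and what the other probes bind stays open.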
